A study of Mus musculus with 32 samples.

How the data were processed

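Methylated RNA immunoprecipitation sequencing was done on liver RNA of 16 male C57BL/6 mice, each with an input and an immunoprecipitated library, 32 samples in all. Per the labels' protocols, total RNA was broken into short fragments, captured with a bead-bound m6A antibody and sequenced on an Illumina NovaSeq instrument. Groups and replicate numbers were taken from the labels: METTL3 HKO, METTL3 flox/flox, RPN11 HKO and RPN11 flox/flox, with 4 mice each.

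The deposited files are 1 peak list per mouse, with genomic position, transcript, gene and annotation terms. Per the submitters' processing notes, cutadapt 1.9.3, HISAT2 2.0.4 and the mm10 build were used; the peak names in the files are those of MACS, whose version and settings are not given in the sources used here. Fold enrichment is a linear ratio over background that the authors deposited for each peak. The column of -10 times log10 of p is a score of the authors' peak caller, per the file headers. The false discovery rate is taken as a percent that the authors deposited. These values belong to their own list and were used only to describe, rank or filter peaks within it. A further score column in each of the 16 lists equalled the -10 log10 p in all 490688 rows and was not used. The lowest -10 log10 p was 3.01, a p of 0.5, and 47 peaks had a false discovery rate under 5%, so the lists are permissive. The files hold no read counts, so depth is unknown and intervals that need it are not given. Start coordinates count from 0 in the files, and printed starts are 1-based.

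Gene symbols were updated through the Entrez identifiers of a RefSeq gene table of GRCm38, the assembly that mm10 names. Of the gene names in the files, 13880 matched by identifier, 276 by synonym, 40 by symbol, and 244 kept their name. Peaks overlapping by at least 1 bp in any mouse were merged into 61416 regions. A region was lost where called in 4 of 4 flox and 0 of 4 HKO mice, and gained in the opposite case. A gene had fewer or more sites where the HKO and flox numbers did not overlap. Chance was taken from the 35 splits of 8 mice into 4 and 4, of which 18 hold 2 HKO mice on each side. A split other than the genotype counted by the larger of its 2 directions.

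Single values per mouse were compared by an exact two-sided permutation test over 70 assignments, whose smallest p is 0.0286. Over 22 lists adjusted by Benjamini-Hochberg, at least 13 lists would need that p for any to pass 0.05. Sites per gene were also tested with limma 3.58.1 in R 4.3.3 on log2(sites + 1), over genes with a site in at least 4 of 8 mice, with Benjamini-Hochberg adjustment; its adjusted p-values are named as such. Effects in the 2 comparisons were set against each other over 4900 label assignments. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

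The methods were tested on simulated data. In 61416 simulated regions of the METTL3 comparison, with calls at 95% in one group and 5% in the other, 65% of 200 lost regions were recovered. For RPN11 the share was 68.5%. Both shares follow from the set call rates and the rule of 4 of 4 against 0 of 4, so they do not measure recovery in the real lists. Of the regions simulated with no difference, 146 were called for METTL3 and 70 for RPN11, in either direction. Real splits with 2 HKO mice on each side gave on average 20 per direction for METTL3 and 40.1 for RPN11. In 9653 simulated genes for METTL3, a 4-fold rise was recovered for 68% of genes by non-overlap and 12% by limma, and a 2-fold rise for 10% and 0%. A 4-fold fall was recovered for 18% by non-overlap and 2% by limma, so 4-fold falls were harder to detect than 4-fold rises, while a 2-fold fall was recovered like a 2-fold rise, for 10% and 0%. In this simulation 1.21% of unchanged genes were called by non-overlap and 0% by limma. For RPN11, with 9896 genes, the shares were 62% and 16% for a 4-fold rise and 28% and 0% for a 4-fold fall, with 1.13% of unchanged genes called by non-overlap. Numbers of sites per gene were simulated as Poisson draws around the flox means of genes with a mean of at least 1. Real numbers can vary less. Psmb2, with 1 site in every METTL3 flox mouse and 2 in every HKO mouse, passed limma (adjusted p = 2.25e-08). Psmb2, Ugt1a1 and S100a9 each had no spread within a group, a change of 1 site and the same limma SE of 0.0092. The small limma p-values of such genes rest on these ties and say little about the size of the change. The simulated shares for genes may therefore not hold for these data.

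Named genes followed a rule fixed before the data were examined: Mettl3, Psmd14 and Acss3, up to 4 separated genes of each list, the 10 largest falls and rises of mean sites per mouse, and the 5 lost and 5 gained regions of highest enrichment. A gene that this rule names in the RPN11 comparison is not reported here. Alternatives were a minimum enrichment of 2.04, equal list lengths (25090 sites for METTL3, 26459 for RPN11), 100 bp bins covered for 50 bp, regions merged within a comparison, 3 of 4 against at most 1 of 4 mice, leaving out each mouse, the replicate number as a block, limma with other settings, and scaling per 1000 sites. Minimums of 50 and 200 on -10 log10 p, a stricter joining of peaks, sites per gene per 1000 sites, limma on list sums, equal list lengths for lists and pathways, pathways without marker genes and leaving out RPN11 HKO mice 2 and 4 were added after the data were seen. The lists fixed in advance hold 449 genes. Planned counts of methylation level per site, of transcript regions and of sequence motifs needed read counts, exon annotation or a genome sequence not used here, and were not run.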

Results

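N6-methyladenosine (m6A) in liver RNA was mapped by methylated RNA immunoprecipitation sequencing, in which RNA fragments captured by an m6A antibody are sequenced beside an input library of the same RNA. Livers came from male C57BL/6 mice in 4 groups of 4. Mice with a hepatocyte-specific knockout (HKO) of METTL3, the catalytic subunit of the m6A writer complex, were compared with METTL3 flox/flox mice. Mice with an HKO of RPN11, a deubiquitylating subunit of the 26S proteasome encoded by Psmd14, were compared with RPN11 flox/flox mice. The 32 samples are 16 input and 16 immunoprecipitated libraries, and the values come from the authors' peak list of each of the 16 mice. A site is 1 listed peak, and the lists hold 490688 sites, between 25090 and 40291 per mouse. They carry no read counts, so sequencing depth and RNA level are unknown, and a gene without a site may be unmethylated or too weakly expressed to be called.

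The METTL3 comparison asks how the set of m6A sites differs when the writer enzyme is deleted in hepatocytes. The METTL3 HKO lists were longer than those of the flox mice. The collagen gene Col4a2, the stellate cell receptor gene Pdgfrb, the endothelial gene Pecam1 and the leukocyte integrin gene Itgb2 had more sites in all 4 HKO mice than in any flox mouse, of which Itgb2 overlapped with equal list lengths. Ugt1a1, which conjugates bilirubin, Gstm1, a glutathione transferase, the lipid droplet gene Cidec and the m6A reader Ythdf2 had fewer. With a minimum of 50 on -10 log10 p, chosen after the data were seen, Itgb2, Cidec and Ythdf2 overlapped, and with a minimum of 200 all 8 of these genes did. HKO mice carried 37319 ± 3338 sites (SD, n = 4) and flox mice 26712 ± 1494 (SD, n = 4), 39.7% more (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows). Without flox mouse 2 the exact p was 0.0571, although all HKO mice (at least 32866 sites) stayed above the remaining flox mice (at most 28710). The number of genes with a site was 11718 ± 266 against 10622.5 ± 61.6 (SD, n = 4 each, exact permutation p = 0.0286). Covered length was 19347 kb against 16545 kb, 16.9% more. Of the additional sites, 66.9% were shorter than 200 bp, and the median site measured 233 ± 25.0 bp in HKO and 332 ± 25.7 bp in flox mice (SD, n = 4 each).

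**Figure D1:**
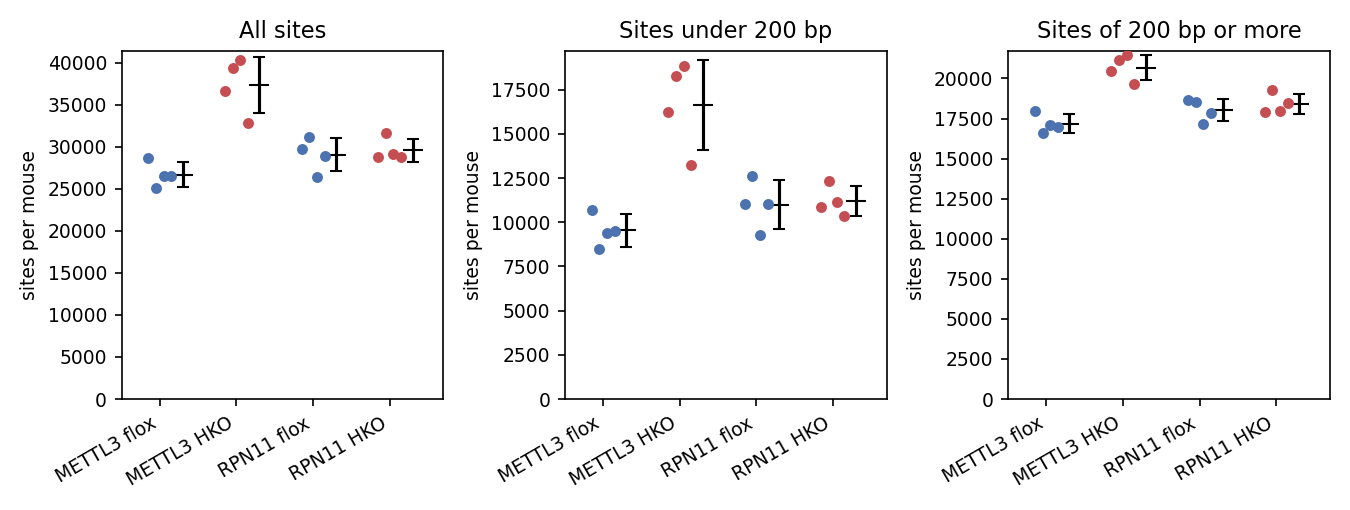
Number of sites per mouse (y axis) in the 4 groups (x axis), for all sites, sites under 200 bp and sites of 200 bp or more; points are mice, and the black mark and bar give mean and SD of 4 mice. The METTL3 HKO mice lie between 32866 and 40291 sites, above the 25090 to 28710 of their flox mice, while the RPN11 groups overlap.

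In the METTL3 HKO, 142 regions called in all 4 flox mice were called in no HKO mouse (lost), and 1548 were called in all 4 HKO mice and no flox mouse (gained), of 56931 regions called in any of the 8 mice. Splits with 2 HKO mice on each side gave on average 20 per direction, and the highest of all other splits 759 in 1 direction, in a split with 3 HKO mice on 1 side. The balance depended on list length: with equal list lengths, the 25090 best-ranked sites of each mouse, 500 regions were lost and 339 gained, against up to 399 in 1 direction in any other split. Lost regions had a median length of 456 bp and an authors' enrichment of 4.52. Gained regions measured 180 bp with an enrichment of 3.82, and regions called in all 8 mice 533 bp with 10.6.

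The strongest lost regions (mm10, with no exon annotation used here) were ranked by enrichment. The first, on chromosome 11 from 115279622 to 115283655, lies in Fads6, a gene of the fatty acid desaturase family, with an authors' enrichment of 25.5 ± 6.99 (SD, n = 4 flox mice). Others lay in Rhou on chromosome 8 (123653929 to 123654216, enrichment 23.1), Ciz1 on chromosome 2 (32363198 to 32363656, 22.4), Nlrc5 on chromosome 8 (94472763 to 94473054, 21.5) and Atf6, a sensor of unfolded protein in the endoplasmic reticulum, on chromosome 1 (170706454 to 170710087, 21.3). The strongest gained regions lay in Eva1b on chromosome 4 (126147744 to 126148631) with 75.6 ± 86.2 (SD, n = 4 HKO mice) and at Grpel1, a mitochondrial protein import gene, on chromosome 5 (36464998 to 36465255) with 49.6 ± 11.2 (SD, n = 4). Pilrb1 on chromosome 5 (137852816 to 137853188), Armcx2 on chromosome X (134804807 to 134807013) and 2010003K11Rik on chromosome 19 (4498244 to 4498583) followed, with 28.8, 28.0 and 26.9.

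**Figure D2:**
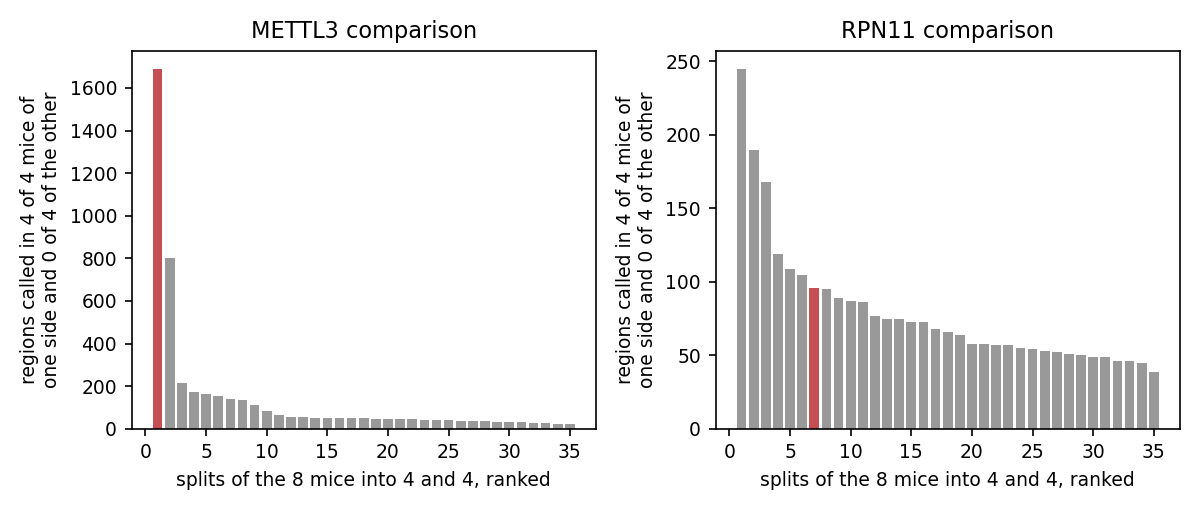
Regions called in 4 of 4 mice of one side and 0 of 4 of the other (y axis) for each of the 35 splits of 8 mice into 4 and 4, ranked (x axis); the red bar is the split by genotype. In the METTL3 comparison the genotype split is the highest, while in the RPN11 comparison another split reaches 245 regions against 96 for genotype.

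By gene, of 13875 genes with a site, 1219 had more sites in all 4 METTL3 HKO mice than in any flox mouse and 70 had fewer, against 13.6 per direction in the splits with 2 HKO mice on each side and up to 463 in 1 direction in any other split. Without ties, chance separates 2.86% of genes. Of the 10 largest rises, Syne2, a nuclear envelope linker, had 14.8 sites in flox and 51 in HKO mice, and Dst 15.2 ± 2.36 and 42.5 ± 11.6 (SD, n = 4 each). Neb went from 9.75 to 30.2 (with equal list lengths the difference was -0.75), Col5a1 from 3.5 to 22.8, Col4a2 from 1 to 20.2, Hspg2, the basement membrane proteoglycan perlecan, from 1.25 to 19.2, and Col6a3 from 10.5 to 28. Tbc1d1, a Rab GTPase-activating protein, went from 4.0 ± 0.816 to 17.8 ± 1.71 (SD, n = 4 each). Myh14 and Myo7a, both myosins, completed the largest rises. The largest falls were on Pclo, from 9.25 ± 1.5 to 3.25 ± 1.71 sites (SD, n = 4 each), and on Tenm3, from 12 to 7.25. Fastkd1 went from 4.75 to 1.5, the nuclear receptor gene Esrrg from 3.25 to 0.25, and Hsd17b6, a steroid dehydrogenase, from 4.75 to 2.25. Tmem28, Tox, Mapk4, Serac1 and Terf1 also fell. Total sites differed by 0.48 on the log2 scale, and per 1000 sites of the mouse 826 genes were higher, all among the 1219, and 2797 lower, a count that takes in genes whose number of sites stayed level. With equal list lengths 225 genes had more sites and 360 fewer, and Syne2, Neb, Myh14, Myo7a, Tox and Terf1 overlapped. With the minimum of 50, 648 genes had more sites and 110 fewer, of which only 244 and 22 were among the 1219 and the 70. Of the genes named for this comparison Syne2, Neb, Col5a1, Myo7a, Fastkd1, Mapk4, Hsd17b6, Serac1, Terf1, Virma, Ythdf2, Psmb2, Cidec, Acadl, Mvk, Scarb1, Csnk1e, Atf3, Mki67, Marco, Itgam, Kdr, Tek, Col1a2, Des, Itgb2 and S100a9 then overlapped. In limma, on numbers not scaled to list length, 1119 of 11462 genes had more and 61 fewer sites at an adjusted p under 0.05. Of the genes named for this comparison by their number of sites, Pclo, Tenm3, Fastkd1, Neb, Col5a1, Myh14, Ythdf2, Gstm1, Kdr, Mettl3, Psmd14 and Acss3 did not pass.

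Marker genes of other liver cells had more sites in the METTL3 HKO, most clearly for stellate and endothelial genes. All 22 gene lists were fixed before the data were examined. The 18 stellate cell and fibrosis genes carried 105 ± 34.9 sites in HKO and 28.8 ± 4.5 in flox mice (SD, n = 4 each), with 5 members higher, 0 lower and 13 not separated. Among them Pdgfrb, a receptor of stellate cells, went from 2 to 13 sites, Col1a2 from 2.25 to 8 and Des from 1 to 2.75. The liver endothelial genes carried 91.2 ± 12.4 against 48 ± 4.55 sites (SD, n = 4 each), with 8 of 14 higher, including Pecam1 (4.75 to 11.5), Ptprb (7.75 to 14.2), Tek and Kdr. The lymphocyte and neutrophil genes carried 17.5 ± 7.19 against 2.25 ± 0.5 (SD, n = 4 each), with 2 of the 11 that had a site higher: Itgb2, the leukocyte integrin chain, went from 0 to 6.75 and S100a9 from 0 to 1. Kupffer cell and macrophage genes carried 48.2 against 29 sites, with Marco (0.5 to 8.75), Timd4 (2.25 to 5.75) and Itgam higher. The cholangiocyte genes carried 26 against 19, with 1 of 11 higher, Krt19 (0 to 2.5).

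Each of these 5 lists had the smallest exact permutation p of 0.0286, as did the m6A writer complex, cholesterol and bile acid, and fetal liver lists, and for all 8 the value adjusted over 22 lists was 0.0786, so none passed. With limma on the list sums, 10 lists passed: these 8, lipogenesis and the 26S proteasome. These sums were not scaled to list length, and total sites differed by 0.48 on the log2 scale. The log2 differences of the writer complex (0.25), cholesterol and bile acid (0.37), cholangiocyte (0.43) and proteasome lists (0.44) lay below that. Those of the other passing lists lay above it. The values were largest for stellate (log2 difference 1.78 ± 0.23 SE, adjusted p = 0.000136), endothelial (0.91 ± 0.12 SE, adjusted p = 0.000136) and lymphocyte and neutrophil (2.44 ± 0.24 SE, adjusted p = 2.64e-05). Per 1000 sites the stellate, endothelial and lymphocyte lists stayed higher in all 4 HKO mice (exact permutation p = 0.0286 each), while the Kupffer (p = 0.143) and cholangiocyte (p = 0.743) lists overlapped. With equal list lengths, chosen for lists after the data were seen, stellate and endothelial genes stayed higher in all 4 HKO mice, by 45.8 and 23.8 sites (exact permutation p = 0.0286 each). The Kupffer (8.5 sites, p = 0.0857), lymphocyte and neutrophil (4 sites, p = 0.143) and cholangiocyte lists (2.25 sites, p = 0.286) overlapped by the same exact test, as did Marco, Timd4, Itgam, Ptprb, Kdr, Tek, Des, Itgb2 and S100a9.

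**Figure D3:**
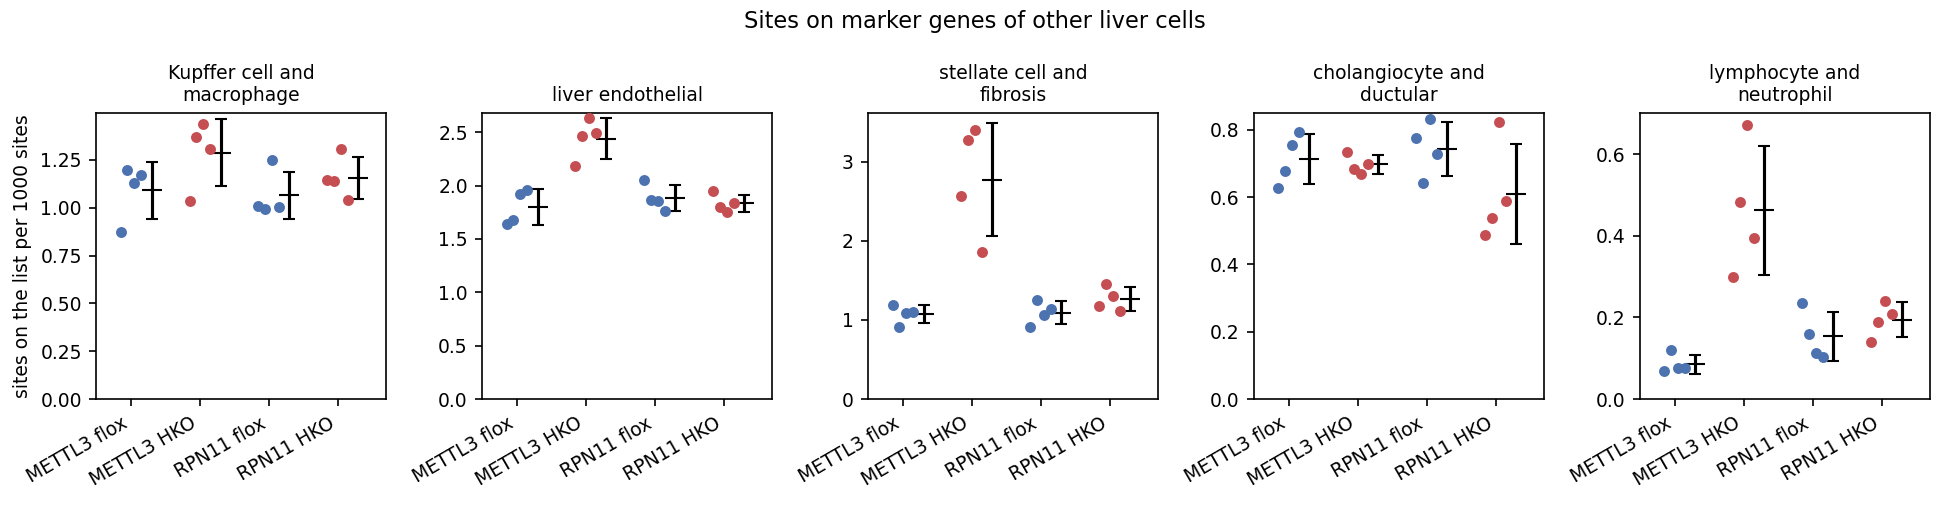
Sites on 5 lists of marker genes per 1000 sites of the mouse (y axis) in the 4 groups (x axis); points are mice, and the black mark and bar give mean and SD of 4 mice. Stellate markers averaged 2.77 in METTL3 HKO and 1.07 in METTL3 flox mice, and cholangiocyte markers 0.698 and 0.713.

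Hepatocyte and housekeeping lists showed few separated members in the METTL3 HKO. Most of these lists turned from higher to lower per 1000 sites, while lipogenesis and fetal liver genes were higher and cytochrome P450 genes lower on both scales. In the cholesterol and bile acid list (72.8 ± 11.6 against 55.8 ± 4.27 sites, SD, n = 4 each), 3 of 26 genes with a site were higher: the mevalonate pathway enzymes Mvk (1.25 to 5.75) and Mvd (0.25 to 3.75), and the HDL receptor gene Scarb1 (1.25 to 4). The 9 writer complex genes carried 45.2 ± 2.87 against 37.8 ± 2.06 sites (SD, n = 4 each), with 1 higher, Virma (7.75 to 10.5), but per 1000 sites the list was lower, at 1.21 against 1.42 (exact permutation p = 0.0286), and the Virma difference was -0.0074. Of 12 eraser and reader genes, Fto was higher (3.75 to 5.25) and Ythdf2 lower (3 to 1.75), but Fto overlapped per 1000 sites and differed by 0 with equal list lengths. In the clock list, Npas2, a partner of BMAL1, went from 0 to 5.75 sites and Csnk1e from 3 to 6.25. Psmb2 (1 to 2) was the only separated proteasome gene of 32. The proteasome list carried 57.5 against 41.8 sites (exact permutation p = 0.0571, limma log2 difference 0.44 ± 0.13 SE, adjusted p = 0.0232), and per 1000 sites 1.53 against 1.57. Acadl (2.25 to 4) in fatty acid oxidation, Atf3 (1.25 to 4) among stress transcription factors, Herpud1 (0 to 2.25) in the unfolded protein list and Mki67 (4 to 8.25) in the fetal and regeneration list were each the only gene higher there. Virma, Csnk1e, Acadl and Mki67, like Kdr, Tek and Neb, overlapped per 1000 sites and with equal list lengths, and Psmb2, Mvd and Scarb1 with equal list lengths. The clock list had 13 fewer sites in HKO mice with equal list lengths (exact permutation p = 0.0286).

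Among triglyceride genes 1 of 30 separated, Cidec, from 2.75 to 0.5 sites. Among the 16 cytochrome P450 and xenobiotic genes with a site, Ugt1a1 (1 to 0) and Gstm1 (2 to 0.75) were lower and none higher. The propionyl-CoA, lipogenesis, glucose and insulin, p53, plasma protein and hepatocyte transcription factor lists had no separated member. As a sum, lipogenesis genes carried 71 ± 23.7 sites in HKO and 41.2 ± 6.99 in flox mice (SD, n = 4 each), which overlapped (exact permutation p = 0.114, limma log2 difference 0.71 ± 0.25 SE, adjusted p = 0.0412), and per 1000 sites 1.87 against 1.54 (exact permutation p = 0.286). Per 1000 sites 8 lists were lower in all 4 HKO mice (exact permutation p = 0.0286 each): writer complex, erasers and readers, propionyl-CoA, fatty acid oxidation, clock, stress transcription factors, cytochrome P450 and hepatocyte transcription factors. The lowest value adjusted over the 22 lists was 0.0571. All of these 8 lists but cytochrome P450 had a higher mean number of sites in HKO mice. Those lists thus rose less than the total, and their lower values per 1000 do not show a loss of sites. By limma, members past the threshold adjusted over all genes numbered 7 of the endothelial and 5 of the stellate list, and 10 and 8 adjusted over the list alone.

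The targeted gene itself could not check the genotype, since peaks carry no RNA level. Mettl3 had 0.5 ± 0.577 sites in METTL3 flox and 1.5 ± 0.577 in HKO mice (SD, n = 4 each), which overlapped. A region on chromosome 14 from 52299701 to 52300105 within Mettl3 was called in 4 of 4 HKO and 0 of 4 flox mice. Psmd14 and Acss3, an acyl-CoA synthetase gene, each had 0.5 and 1 sites in METTL3 flox and HKO mice and overlapped.

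The authors' enrichment over input also depended on which sites were taken. The median over all listed sites was 5.27 ± 0.172 in METTL3 HKO and 5.94 ± 0.217 in flox mice (SD, n = 4 each, exact permutation p = 0.0286). Over the 15181 regions called in all 8 mice it was higher in the HKO, 11.2 ± 0.144 against 10.01 ± 0.535 (SD, n = 4 each, exact permutation p = 0.0286). Each enrichment is relative to its own list, so these medians describe the lists and are not methylation levels.

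The RPN11 comparison asks how m6A sites differ when RPN11 is deleted in hepatocytes. No gene list separated the genotypes by its number of sites, and other groupings of the same mice separated up to 109 genes in 1 direction, against 32 fewer and 70 more for genotype. Esr1, the estrogen receptor gene, had 4.25 ± 1.26 sites in RPN11 flox and 2 ± 0 in HKO mice (SD, n = 4 each), but did not pass limma (adjusted p = 0.403). Adamtsl2, an extracellular matrix gene, had 3.75 ± 0.5 and 7.5 ± 0.577 (SD, n = 4 each). With the minimum of 50 on -10 log10 p both overlapped, and the Adamtsl2 difference was 0. RPN11 HKO mice carried 29594 ± 1366 sites and flox mice 29048 ± 1970 (SD, n = 4 each, exact permutation p = 0.771). The median enrichment was 5.48 ± 0.288 against 5.81 ± 0.266 (SD, n = 4 each, exact permutation p = 0.2).

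By region, 35 were lost and 61 gained in the RPN11 HKO, against 40.1 per direction in splits with 2 HKO mice on each side. The strongest lost regions lay in Gm8989 on chromosome 7 (106322996 to 106324528, enrichment 20.0), in Cdo1, cysteine dioxygenase, on chromosome 18 (46727973 to 46728342, 7.08) and in Sema3b on chromosome 9 (107600828 to 107601047, 7.02), followed by Cct7 and Tnfrsf19. The strongest gained regions lay in Gid8 on chromosome 2 (180716859 to 180717056, 21.3), at Serpina3c on chromosome 12 (104146382 to 104147423, 17.2 ± 27.2, SD, n = 4) and in Rgs3 on chromosome 4 (62701034 to 62701200, 13.6), followed by Cct8 and Ylpm1.

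By gene, 32 had fewer and 70 more sites in the RPN11 HKO, against 30.1 per direction in splits with 2 HKO mice on each side. Fewer sites were listed on Caln1 (5.5 to 3.25), Pecam1 (7 to 5), Dab2 (4.5 to 2.5), Ube2s (3.25 to 1.25), Pgap1 (2 to 0), Gtf3c4, Nipal3 and Med1. More were listed on Srgap2 (10.8 to 15.2), Stk10 (6.75 to 11), Bod1l (12.5 to 16.5), Wdfy4 (4.5 to 8.25), Svil (9.5 to 13), Ncam2 (1.5 to 4.5), Rock1 (6.25 to 9), Rbm26 (1.75 to 4.5) and Ofd1 (0.75 to 3.5). In limma, 11 genes had fewer and 29 more sites at an adjusted p under 0.05, including Pgap1 (log2 difference -1.54 ± 0.20 SE, adjusted p = 0.044) and Adamtsl2 (0.84 ± 0.09 SE, adjusted p = 0.019). None of the other genes named for this comparison by their number of sites passed limma. With equal list lengths Pecam1, Ube2s, Pgap1, Gtf3c4, Nipal3, Med1, Srgap2, Bod1l, Wdfy4, Svil, Ncam2 and Rbm26 overlapped. With only sites of -10 log10 p of at least 50, a setting chosen after the data were seen, 54 genes had fewer and 8 more. Of these only 4 and 1 were among the 32 and the 70. At this minimum all genes named here overlapped, and the Wdfy4 difference was -0.5. The median -10 log10 p was 50.1 and 52.3 in HKO mice 2 and 4, 91.2 and 121 in HKO mice 1 and 3, and 92.4 to 126 in flox mice.

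Across the 22 lists in the RPN11 comparison, 1 member separated, Pecam1, and the lowest adjusted permutation p was 0.864. The 27 proteasome genes with a site carried 40.8 ± 1.89 sites in HKO and 40.8 ± 4.35 in flox mice (SD, n = 4 each). Lipogenesis genes carried 46 ± 4.55 against 47 ± 13.8 (SD, n = 4 each), triglyceride genes 58.2 against 60.2, fatty acid oxidation genes 53.8 against 59 and propionyl-CoA genes 43.5 against 45. Fetal liver genes carried 13.8 ± 1.26 against 11.5 ± 1 (SD, n = 4 each, exact permutation p = 0.0571). Stellate genes carried 37.5 against 31.8, endothelial genes 54.2 against 54.8 and Kupffer genes 34.2 against 30.8 sites. Psmd14 had 0.5 sites in RPN11 flox and 1 in HKO mice, Mettl3 0.75 in both and Acss3 1 in both, all overlapping. By limma 0 lists passed after adjustment and 1, the fetal liver list, had an unadjusted p under 0.05, and by permutation 0 had an unadjusted p under 0.05. Per 1000 sites the fatty acid oxidation list was lower in all 4 HKO mice, 1.82 against 2.03 (exact permutation p = 0.0286, adjusted 0.419), and with equal list lengths the propionyl-CoA list was lower by 5 sites (exact permutation p = 0.0286).

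The HKO effects of the 2 comparisons were set against each other by exchanging the comparison labels within HKO and within flox mice. The effect on the number of sites was larger in the METTL3 comparison by 10060.5 sites (permutation p = 0.00204). So were the effects on endothelial (by 43.8 sites, adjusted permutation p = 0.0269), stellate (70.8, 0.0305), lymphocyte and neutrophil (14, 0.0269), cholangiocyte (10.5, 0.0305) and cholesterol and bile acid genes (21.2, 0.0305), adjusted over 22 lists. These differences are in sites not scaled to list length.

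Sites lost in one HKO were then counted in the mice of the other comparison. Of the 142 regions lost in the METTL3 HKO, RPN11 HKO mice had 98.8 ± 8.88 and RPN11 flox mice 106 ± 11.9 (SD, n = 4 each, exact permutation p = 0.4). Of the 35 lost in the RPN11 HKO, METTL3 HKO mice had 17 ± 2.58 and METTL3 flox mice 13.8 ± 0.957 (SD, n = 4 each, exact permutation p = 0.0857), and with equal list lengths the HKO mice had 7.5 fewer in place of more. Among 16622 regions called in all 8 flox mice, 59 were lost in the METTL3 HKO, 4 in the RPN11 HKO and 0 in both (Fisher's exact test p = 1). With regions called in at least 3 of 4 flox and at most 1 of 4 HKO mice, 92 were lost in both against 12.7 for independent sets (Fisher's exact test p = 7.32e-54). That background was not matched for site strength, and regions of 1 gene are not independent, so this p overstates the evidence. By non-overlap, 1 gene had fewer sites in both HKOs (Fisher's exact test p = 0.148). Of the 1056 regions lost in the RPN11 HKO by the rule of 3 of 4 mice, METTL3 HKO mice had more, 586 ± 72.4 against 435.5 ± 65.3 in METTL3 flox mice (SD, n = 4 each, exact permutation p = 0.0286). The 2 flox groups differed in 108 regions, against a mean of 61.9 in splits with 2 mice of each group on each side.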

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

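The tests of weak peaks, of markers per 1000 sites and with equal list lengths, of each marker list and of the splits by regions and genes were chosen after the result was seen, and the others before. In 120 groups of 4 mice, 9 held a mouse far from its group by the gap over the range. About 1 in 20, or 6, would by chance if values had no ties. Where the other 3 mice tie, any gap passes this rule, as for 3 against 2 sites on lymphocyte and neutrophil genes, so that share does not hold for small counts.

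METTL3 HKO mice had more sites than their flox mice, the opposite of what losing the writer enzyme would be expected to give. With -10 log10 p of at least 50 the genotype split still gave 759 gained regions, above the 430 of any other split. These regions were called anew from peaks of at least 50, so they need not be among the 1548 gained without a minimum. Of the 648 genes with more sites at this minimum, 244 were among the 1219 without it. Such a minimum only moves the calling limit, so it cannot exclude peaks near a limit as a cause. The 1548 gained regions had a median -10 log10 p of 27.1, against 442 for regions called in all 8 mice. Read depth, which is unknown, was not tested, so a technical and a biological origin are both possible here. Equal list lengths, with 339 gained regions against 399 in another split, decide nothing, since they remove the difference in sites by design. Whether a library carries another genotype than its label was not tested.

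Marker genes of other liver cells had more sites in the METTL3 HKO. Longer lists alone are argued against for the 5 lists together, which were higher by 2.90 per 1000 sites (7.66 ± 1.04 against 4.76 ± 0.329, SD, n = 4 each) and by 84.2 sites with equal list lengths (202.5 against 118, exact permutation p = 0.0286 for both), and for stellate (by 45.8) and endothelial genes (23.8), but stay open for Kupffer (8.5), lymphocyte and neutrophil (4) and cholangiocyte genes (2.25), which overlapped with equal list lengths. A larger gain of genes with many sites is argued against too, since the ratio of 2.27 lay above a median of 1.42 in 10000 gene sets matched on sites. More RNA of other cells in these livers is a candidate explanation that cannot be told apart from a change of methylation, since RNA levels were not analysed here. Per 1000 sites 3 of 5 lists were higher in all HKO mice and 0 lower, while Kupffer and cholangiocyte genes overlapped. What would count against this explanation was reworded after the result was seen. The ratios per 1000 sites were 1.18 for Kupffer, 1.36 for endothelial, 2.59 for stellate, 0.979 for cholangiocyte and 5.43 for lymphocyte and neutrophil genes.

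In the RPN11 comparison, a split of HKO mice 1 and 3 with flox mice 2 and 4 against the rest separated 245 regions, where genotype separated 96. Unequal list lengths are argued against, since with equal lengths that split still separated 257, above the 132 of any other. On its other side, HKO mice 2 and 4 had the lowest median -10 log10 p of these 8 mice, 50.1 and 52.3, where the other HKO mice had 91.2 and 121 and the flox mice 92.4 to 126. It points to a structure of these mice that no label names, and no biological explanation was tested.

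Of the 35 splits of 8 mice, each but the genotype counted by the larger of its 2 directions, only the genotype gave as many as 1548 gained METTL3 regions (highest other 759), 1219 genes with more sites (463) and 1180 limma calls (180), 1 of 35 each. That is the smallest share these splits allow, without adjustment over the counts, so chance is unlikely but not excluded. Chance stays open for the 142 lost METTL3 regions (as many in 3 splits, highest other 759) and the 70 genes with fewer sites (8 splits, 463). For these the highest other counts were gains in a split with 3 HKO mice on 1 side (41 regions and 18 genes in its other direction). With equal list lengths only the genotype gave as many losses, 500 regions (highest other 399) and 360 genes (215), 1 of 35 splits each. This setting drops more sites from HKO than from flox lists, which favours losses by design, so it cannot exclude chance. With a minimum of 200 on -10 log10 p, chosen after the data were seen, 238 regions (213) and 178 genes (163) also came in 1 of 35 splits each. With the minimum of 50, as many came in 2 splits each for 188 regions (430) and 110 genes (294). The settings thus differ, and chance cannot be excluded for these losses. In the RPN11 comparison it cannot either: as many came in 20 splits for 35 lost regions, 9 for 61 gained (highest other 174 for both), 20 for 32 genes with fewer and 4 for 70 with more sites (109 for both), and 2 for 40 limma calls (42). Nor can it for the 108 regions between the flox groups, with as many in 5 splits (highest 293).

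Mice far from their group were RPN11 HKO mouse 2 with 31630 sites (others 28771, 29130 and 28843) and with 66 on triglyceride genes (56, 55 and 56), and RPN11 HKO mouse 4 with 33 on unfolded protein genes (36 in each other). METTL3 HKO mouse 4 had 41 on writer genes (46, 47 and 47) and 23 on cholangiocyte genes (27 in each). RPN11 flox mouse 1 had 44 on writer genes (38, 37 and 37) and 13 on fetal genes (11 in each), METTL3 flox mouse 1 had 25 on Kupffer genes (30, 30 and 31), and METTL3 flox mouse 2 had 3 on lymphocyte and neutrophil genes (2 in each).

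The HKO effect was larger in the METTL3 than in the RPN11 comparison by 10060.5 sites in all (permutation p = 0.00204), and by 21.2 on cholesterol and bile acid, 43.8 on endothelial, 70.8 on stellate, 10.5 on cholangiocyte and 14 on lymphocyte and neutrophil genes (adjusted permutation p between 0.0269 and 0.0305).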

How the results depend on the processing

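Minimums of 50 and 200 on -10 log10 p, joining peaks by overlap of the shorter peak, sites per gene per 1000 sites, limma on list sums, equal list lengths for lists and pathways, pathways without marker genes and leaving out RPN11 HKO mice 2 and 4 were chosen after the data were seen, and the other settings before. Higher site numbers in the METTL3 HKO kept their direction in every setting run on them. The difference lay between 9616 and 12091 with 1 mouse left out (p = 0.0571 by exact permutation without flox mouse 2, though the groups did not overlap). With the minimum of 50 on -10 log10 p it was smaller, 4706 sites or 29.2% more (exact permutation p = 0.0286). Depth is unknown, and p-values between 4 and 4 mice end at 0.0286. Planned counts of methylation level, transcript regions and motifs, with their settings, were not run. Calling a region by an overlap of at least 0.5 of the shorter was void, since a peak always lies within its region and 0 calls changed. A fold minimum, merging within a comparison and stricter joining moved no count of regions or genes by over 1.5 times. Of 52 METTL3 genes named, 26 held direction and side of the threshold with equal list lengths, 25 with the minimum of 50 and 44 per 1000 sites. Of 23 RPN11 genes these were 9, 2 and 22. Unless said, the cause of a change was not tested.

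In the METTL3 comparison, equal list lengths gave 500 lost and 339 gained regions and 360 genes with fewer and 225 with more sites. A minimum of 50 on -10 log10 p gave 759 gained regions and 110 and 648 genes, and a minimum of 200 gave 238 and 427 regions and 178 and 372 genes. Bins of 100 bp gave 1191 and 5263, and 3 of 4 against at most 1 of 4 mice 1455 and 8744. Per 1000 sites 2797 genes were lower. Of 12 pathways for genes with more sites, 4 passed without marker genes and 3 with equal list lengths. In the RPN11 comparison the minimum of 50 gave 59 and 15 regions and 54 and 8 genes, the minimum of 200 gave 11 gained regions and 52 and 10 genes, bins gave 218 and 317, and 3 of 4 mice gave 1056 and 1214. Per 1000 sites 93 genes were lower and 108 higher. Without HKO mice 2 and 4 there were 252 and 335 regions and 203 and 215 genes, where fewer mice loosen the criterion. In limma 11 genes had fewer and 29 more sites, also with a pseudocount of 0.5. For site totals, RPN11 HKO mice had -20.1 kb of covered length and -1201.5 sites with the minimum of 50, against flox mice.

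The replicate number did not pair the mice: same-numbered mice correlated between -0.0906 and 0.0858, and not every mouse correlated best with its own number. With the replicate block, the METTL3 difference of 10606.5 sites had an exact p of 0.125, the smallest that 4 pairs allow, and 0 lists passed that test for the same reason. Limma on list sums with the replicate block passed all but the writer complex of its 10 METTL3 lists (adjusted p = 0.087 for writers, from 0.0412). Limma with the replicate block gave 502 METTL3 genes with more sites, and 12 fewer and 26 more for RPN11.

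Leaving out 1 mouse loosens the criterion by construction. The METTL3 ranges were 172 to 557 lost (557 without HKO mouse 1, 232 without HKO mouse 4, 220, 219 and 216 without flox mice 1, 2 and 4), 1730 to 3720 gained (3720 without HKO mouse 4, 2904 without HKO mouse 1), 82 to 278 genes with fewer sites (278 without HKO mouse 1, 112 without HKO mouse 4, 114 and 107 without flox mice 2 and 4) and 1314 to 2136 with more (2136 without HKO mouse 4, 1936 without HKO mouse 1). The RPN11 ranges were 77 to 115 lost, 95 to 151 gained, 60 to 96 genes with fewer and 95 to 152 with more sites, where every mouse left out moved each count by over 1.5 times, except HKO mouse 2 and flox mouse 4 for genes with more sites. RPN11 site totals ranged from -317 without flox mouse 3 to 1252, and were -133 without HKO mouse 2. The METTL3 enrichment difference ranged from -0.760 to -0.588 (exact p = 0.0571 without flox mouse 3) and was 1.20 over regions called in all 8 mice. With 1 flox mouse left out, an exact p can exceed 0.05 though the groups do not overlap, as for site totals without flox mouse 2. The 8 METTL3 lists at an unadjusted p under 0.05 ranged from 2 without any 1 flox mouse to 13 without HKO mouse 4. They were 4 by list genes with a site, 4 with the minimum of 50 and 3 with equal list lengths. For RPN11 lists the range was 0 to 1, with 1 without HKO mouse 3 or flox mouse 3, and 1 per 1000 sites and with equal list lengths (propionyl-CoA genes, -5). Sites lost in the RPN11 HKO differed in METTL3 mice by 2.25 to 4.25 (exact p = 0.0286 without HKO mouse 3), by -7.5 with equal list lengths, -0.0531 per 1000 sites and 150.2 with 3 of 4 mice. The overlap of lost regions was 1 with equal list lengths, 92 with 3 of 4 mice and 1 for genes, and the flox groups differed in 176 regions without METTL3 flox mouse 2 to 343 without RPN11 flox mouse 3, over 1.5 times the 108 for every mouse left out.

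Among named genes these turned negative in the HKO: with equal list lengths Mettl3, Psmd14 and Acss3 (-0.25 each) and Neb (-0.75) for METTL3 and Psmd14 (-0.25) for RPN11, per 1000 sites Virma (-0.0074), and for RPN11 with the minimum of 50 Psmd14 (-0.25) and Wdfy4 (-0.5) and with 200 Stk10 (-0.25) and Wdfy4 (-0.75).

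METTL3 list differences turned negative per 1000 sites for writers (-0.202), erasers and readers (-0.202), proteasome (-0.0320), propionyl-CoA (-0.195), triglyceride (-0.398), fatty acid oxidation (-0.507), cholesterol (-0.130), glucose (-0.1497), clock (-0.333), stress factors (-0.406), p53 (-0.161), unfolded protein (-0.260), plasma protein (-0.136), hepatocyte factor (-0.209) and cholangiocyte genes (-0.0149). By list genes with a site they did so for propionyl-CoA and triglyceride (-0.25 each), fatty acid oxidation and glucose (-0.5 each) and plasma protein genes (-1), and with the minimum of 50 for fatty acid oxidation (-3), clock (-6.75), p53 (-0.25) and unfolded protein genes (-1). With equal list lengths they did so for writers, proteasome and glucose (-0.75 each), erasers and readers (-0.5), propionyl-CoA (-5.25), triglyceride (-10.2), fatty acid oxidation (-8.5), clock (-13), stress factors (-1.25), p53 (-3.75) and unfolded protein genes (-2). Plasma protein genes ranged from -0.583 without flox mouse 2 to 2.42. For RPN11, list genes with a site reversed erasers and readers (-0.5), propionyl-CoA (0.75), triglyceride (0.5), stress factors (-0.25), p53 (1.5), plasma protein (0.75), endothelial (0.25) and cholangiocyte genes (0.5), and the minimum of 50 reversed writers, stress factors and Kupffer genes (-1.25 each) and clock genes (-1.75), and equal list lengths plasma protein genes (0.25). RPN11 HKO mice 2 and 4, of the lowest median -10 log10 p (50.1 and 52.3), bear on the minimum of 50. With 1 mouse left out, RPN11 lists that turned direction, none of which separated the genotypes, ranged from -1.42 to 0.833 for plasma protein, -2.17 to 0.167 for cytochrome P450, -2.42 to 1.58 for endothelial, -5.67 to 5.33 for lipogenesis, -2.5 to 0.5 for propionyl-CoA, -4.75 to 0.25 for triglyceride, -1.83 to 0.167 for p53 and -3 to 1 for hepatocyte factor genes.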

Other observations

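The pathway and gained-region tests here were chosen after the results were seen. Genes with more sites in the METTL3 HKO were more frequent in several pathways, among them cytoskeleton, adhesion and leukocyte migration, by the KEGG terms of the authors' annotation. For regulation of the actin cytoskeleton, 39 of 169 genes had more sites (23.1%), where 19.4 were expected for genes with as many sites (exact one-sided test within 10 classes of site number, adjusted p = 0.00133 over 277 pathways). Focal adhesion held 38 of 167 (20.1 expected, adjusted p = 0.00389), leukocyte transendothelial migration 21 of 93 (10.7 expected, adjusted p = 0.0366) and ECM-receptor interaction 15 of 63 (6.91 expected, adjusted p = 0.0467). In all, 12 pathways passed this test, and 18 passed a one-sided Fisher's exact test that takes no account of site number, with 10 passing both. Others past both were proteoglycans in cancer, Rap1 signaling, platelet activation, amoebiasis, glioma, and protein digestion and absorption. Of 4917 genes with a pathway, 9.40% had more sites. Marker genes of other liver cells, whose 5 lists carried 7.66 against 4.76 sites per 1000, were a minority of the called members in all 12. They were 4 of 21 in leukocyte migration (Pecam1, Cdh5, Itgam and Itgb2) and 3 of 39 in actin cytoskeleton. In focal adhesion they were 4 of 38 (Col1a2, Col4a2, Pdgfrb and Kdr), and in ECM-receptor interaction 2 of 15 (Col1a2 and Col4a2). Without the marker genes 4 of the 12 passed the matched test, actin cytoskeleton (36 of 166, adjusted p = 0.00664), focal adhesion (0.0113), and platelet activation and proteoglycans in cancer (0.0247 each). Leukocyte migration (0.176) and ECM-receptor interaction (0.0741) did not. With equal list lengths, where 192 of the 1219 genes kept their call, 3 of the 12 passed, ECM-receptor interaction (0.00313), focal adhesion and protein digestion (0.0088 each), while actin cytoskeleton and leukocyte migration (1 each) did not. Examples, chosen after their values were seen, are Actn1, an actin crosslinker (3.75 ± 1.5 to 13.8 ± 2.87 sites, SD, n = 4 each), the integrin gene Itga9 (3.25 to 11.2), Pdgfra (3.75 to 11), the leukocyte GTPase gene Rac2 (0.5 to 3.5) and the adhesion receptor gene Vcam1 (3.5 to 5). Pathways share genes and are not independent. By the matched test 0 pathways passed for genes with fewer METTL3 sites (9 at an unadjusted p under 0.05, 8 by Fisher's exact test, 0 adjusted). For RPN11 0 of 275 passed either test, with 3 for fewer and 9 for more sites at an unadjusted matched p under 0.05 (3 and 6 by Fisher's exact test).

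Of the 61 regions gained in the RPN11 HKO, METTL3 HKO mice had 42.2, between 37 and 46, and METTL3 flox mice 17.2, between 14 and 22 (n = 4 each, exact permutation p = 0.0286), and per 1000 sites 1.14 against 0.643 (exact permutation p = 0.0286). As many as 61 came in 9 of 35 splits of the RPN11 mice. METTL3 HKO mice called 32317 to 39736 regions in all and METTL3 flox mice 24476 to 28162, with 15181 called in all 8. No background of regions called in only some mice was used. A shared gain therefore cannot be told apart from longer lists. Of the 1548 gained in the METTL3 HKO, RPN11 HKO mice had 475 ± 93.3 and RPN11 flox mice 368 ± 125 (SD, n = 4 each, exact permutation p = 0.2).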
